A study of Homo sapiens with 28 samples.

How the data were processed

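The series holds 28 samples of human term placental villous tissue, of which 4 were single-cell libraries and 24 were bulk libraries in 8 groups. The design text counts 5 placentas, and gives 2 as the source of the single-cell libraries, each run with a technical replicate. Per the labels' protocols, villous tissue was dissected free of the basal and chorionic plates and dissociated with enzymes. Red blood cells were then lysed, the suspension was passed through size filters, and droplet libraries were made with the 10x Genomics Chromium 3′ chemistry, per the same labels. Per the submitters' processing notes, Cell Ranger, Seurat, STAR 2.6.0c, featureCounts of Subread 1.6.1 and DESeq were used on the series with the GRCh38.p12 genome. The notes give these tools no role or order. Bulk samples were not analysed here, because the only table available held single cells.

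The authors deposited 1 table of whole-number counts, with 16003 genes and 40494 cells. Its column names give a cell type for each cell, 27 in all, of which 19 begin with Fetal and 8 with Maternal. How cells were assigned to a type or an origin is not stated in the labels, so the names were used as given. No column name ties a cell to a library or a placenta, and the table was therefore treated as 1 pooled sample. The labels do not state which libraries its columns came from, so it may hold cells from outside those 2 placentas. Cell totals ran from 498 to 120147 counts with a median of 2580. The lowest total of any gene was 100 counts, the fewest genes in a cell was 195, and no cell had more than 9.21% of its counts from mitochondrial genes. Those limits are properties of the table as deposited, and the filters that gave rise to them are not recorded.

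Counts were summed over the cells of each type and scaled by the type's total to CPM, the usual per-library unit. Types were compared as log2 ratios of CPM after adding 1 CPM to each side. A pooled sample has no replicates, so no test was run and no p-value was computed. CPM values carry 95% exact Poisson intervals and shares carry 95% exact binomial intervals (Clopper-Pearson), and both cover counting error only. A count of 0 was taken to allow up to 3 counts. Neither interval covers differences between placentas or between libraries.

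Before the data were examined, 28 gene lists of 265 distinct genes were fixed, as were the rule for naming genes, all comparisons but that of CD14+ monocytes, and all alternatives but 3. A gene was eligible in a comparison when it had at least 50 CPM and was found in at least 10% of cells in the type where it was higher. Each trophoblast type was represented by the 7 eligible genes with the largest log2 ratio to the highest other trophoblast type. Stromal and endothelial types were represented by 8 genes each, chosen in the same way. Hofbauer cells and maternal monocytes were represented by 12 genes in each direction. For the 4 lymphocyte types found in both origins, the rule took the 10 genes in each direction whose smallest log2 ratio over the 4 types was largest, at 20 CPM or more in the higher side of each. Mitochondrial and ribosomal protein genes were left out of these rankings. A further 20 genes, sex-linked or variable between people by deletion or rearrangement, were not written out at all.

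For each list, the median log2 ratio of eligible members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of this table only. List members were called higher or lower at a ratio of at least 2-fold, a size chosen after the values were seen. Profiles were compared by Pearson correlation across genes of log2(CPM + 1), over genes with at least 10 CPM in any type. Genes are not independent replicates. Shares of cells with a count depend on depth, so for 4 transcripts and for the marker tests cells with at least 1000 counts were also thinned at random to 1000. Gene positions come from GENCODE 44 on GRCh38, matched by symbol for 14353 genes, while 1650 symbols were not found there.

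The alternatives were the mean of per-cell CPM, a pseudocount of 10 or 0.1 CPM, totals without the 20 most abundant genes of any type, and median-of-ratios size factors. Others left out the 5% deepest cells of each type or the cells under 1000 counts, thinned each cell to 1000 counts, or dropped the filter on low values. Correlations were repeated at 1 and 100 CPM, with Spearman's coefficient, and with each type thinned to the total of the smallest type. No doublet caller was run, because the libraries cannot be separated. The 4 choices added after the data were seen were lymphocyte rankings without the CD8+ activated T pair, rankings without the naive CD8+ T pair, CD14+ cells alone as the maternal monocytes, and a comparison of fetal with maternal CD14+ monocytes. Also chosen then were the single value followed through the alternatives for each comparison, the pairing of 17 lists with type names, and the genes described as such below. The calculation was tested on simulated counts for the 11 pairs of types compared, with 200 genes raised in each. Both simulated types of a pair shared 1 real profile, so the other genes differed by counting error only. Simulated ratios were centred on the median of the unchanged genes, a step not used for the ratios reported here. At 2-fold, at least 95.9% of changed genes were recovered within 0.5 log2 units in every pair, and at 4-fold at least 96.1%. In each simulated pair the top 12 genes were all changed genes, which was near certain because no other gene differed beyond counting error. The simulation therefore covers counting error, and not the shifts from scaling described below. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.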

Results

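Single-cell profiles of villous placenta at term were pooled in 1 table of 40494 cells and 170242166 counts. The series was built as a reference of placental cell types, against which bulk placental profiles can be split into the shares of their cells, with preeclampsia as the setting. The profiles cover trophoblasts, stromal and endothelial cells of the villous core, Hofbauer cells (the fetal macrophages of the villus), and leukocytes named fetal or maternal. Because cells could not be assigned to a library or placenta, and the number of placentas behind the table is not known here, every value below comes from 1 pooled sample with no replicates.

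Fetal cells were the larger part of the reference, and mesenchymal cells were the largest type among them. Types named fetal held 34165 cells, or 84.4% of the total (95% interval 84.0 to 84.7). Cells named mesenchymal stem cells numbered 12236, which was 35.8% of fetal cells (35.3 to 36.3), and trophoblasts made up 31.2% (30.7 to 31.7). Hofbauer cells made up 9.12% of fetal cells (8.82 to 9.43). Among the 10672 trophoblasts, 38.9% were extravillous (38.0 to 39.9) and only 384 cells, or 3.60% (3.25 to 3.97), were named syncytiotrophoblast, the multinucleate layer that covers the villus. Counts per cell differed widely between types, with a median of 7893 in cytotrophoblasts, 6018.5 in extravillous trophoblasts, 1236.5 in syncytiotrophoblast and 1283 in Hofbauer cells. Cells under 1000 counts made up 16.6% of the table. The labels do not say how cells were chosen for the reference, and the suspension had been size-filtered, so these are shares of the table and not of the tissue.

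**Figure D1:**
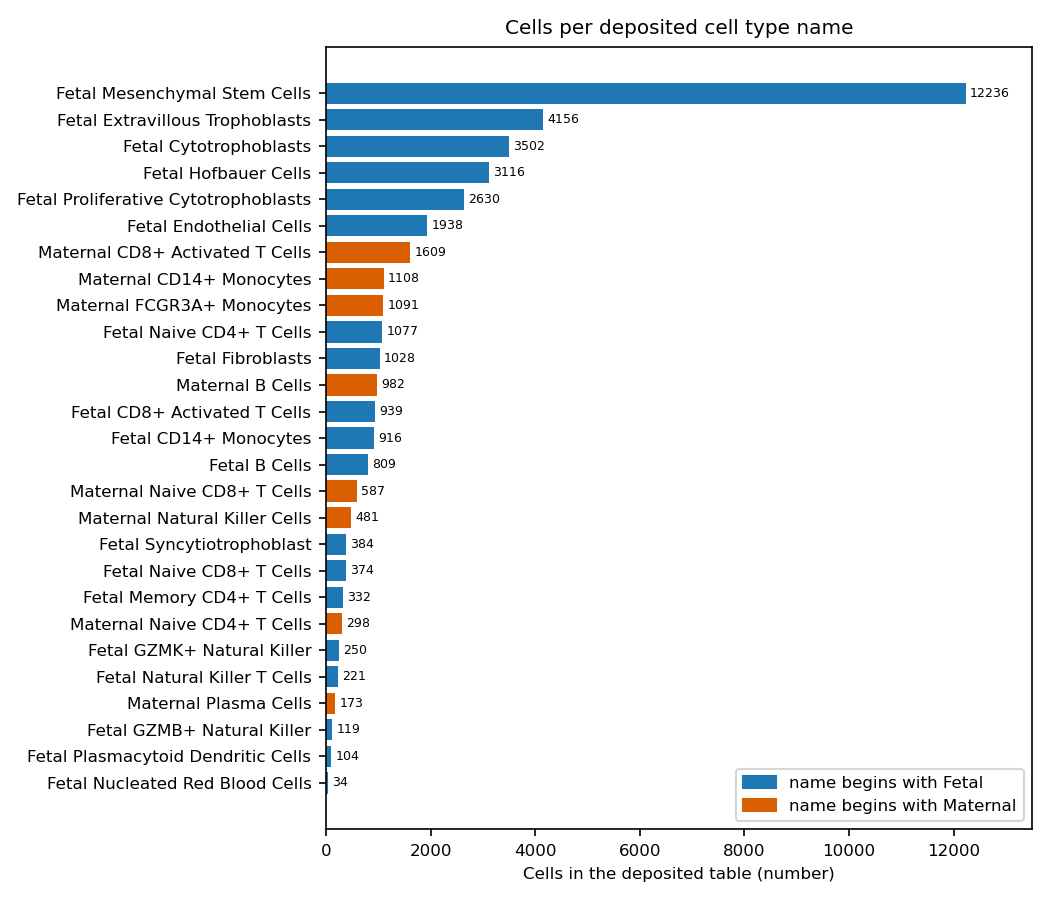
Horizontal bars give the number of cells in the deposited table (x axis) for each of the 27 cell type names (y axis), coloured by whether the name begins with Fetal or Maternal. Mesenchymal stem cells are the longest bar at 12236 cells, and nucleated red blood cells the shortest at 34.

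The names given to the cells were compared with marker lists fixed in advance, though the pairing of lists with names was chosen after the values were seen. For 16 of the 17 lists paired with a name or part of a name, the type with the highest median level carried it, whether fetal or maternal. Markers of syncytiotrophoblast, cytotrophoblast, extravillous trophoblast, Hofbauer cells, endothelium and red cells were each highest in the type so named. The exception was the perivascular list, which holds contractile genes such as ACTA2 and MYH11 and was paired with the mesenchymal name, but was highest in the cells named fibroblasts. By the mean of each list in place of the median, 14 of 17 matched, since the FCGR3A+ monocyte list was then highest in Hofbauer cells and the fibroblast list in mesenchymal stem cells. A match of the highest type does not check the names of the others. The natural killer list was 10.14 in fetal GZMB+ natural killer cells and 10.10 in fetal CD8+ activated T cells. No list was made for plasmacytoid dendritic cells.

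The most abundant hormone transcript of the syncytiotrophoblast was found in every other type. CSH1, which encodes placental lactogen, made up 209514 CPM in syncytiotrophoblast and 12470.9 CPM in extravillous trophoblasts. It was 55.4 CPM in maternal B cells and 254 CPM in fetal GZMK+ natural killer cells. After thinning to 1000 counts per cell, CSH1 was found in 94.5% of syncytiotrophoblast cells (90.8 to 97.1) and still in 6.37% of maternal B cells (4.91 to 8.09), which should lack it. Before thinning, at median depths of 1236.5 and 3523.5 counts, these shares were 93.8% and 16.2%. HLA-G, a class I molecule of extravillous trophoblasts, was found in 71.8% of thinned extravillous cells (70.4 to 73.2) and in 0.103% of maternal B cells. PAGE4, a cytotrophoblast transcript, was found in 96.7% of thinned cytotrophoblasts and 1.33% of maternal B cells, but in 35.6% of fetal GZMK+ natural killer cells (29.3 to 42.3).

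**Figure D2:**
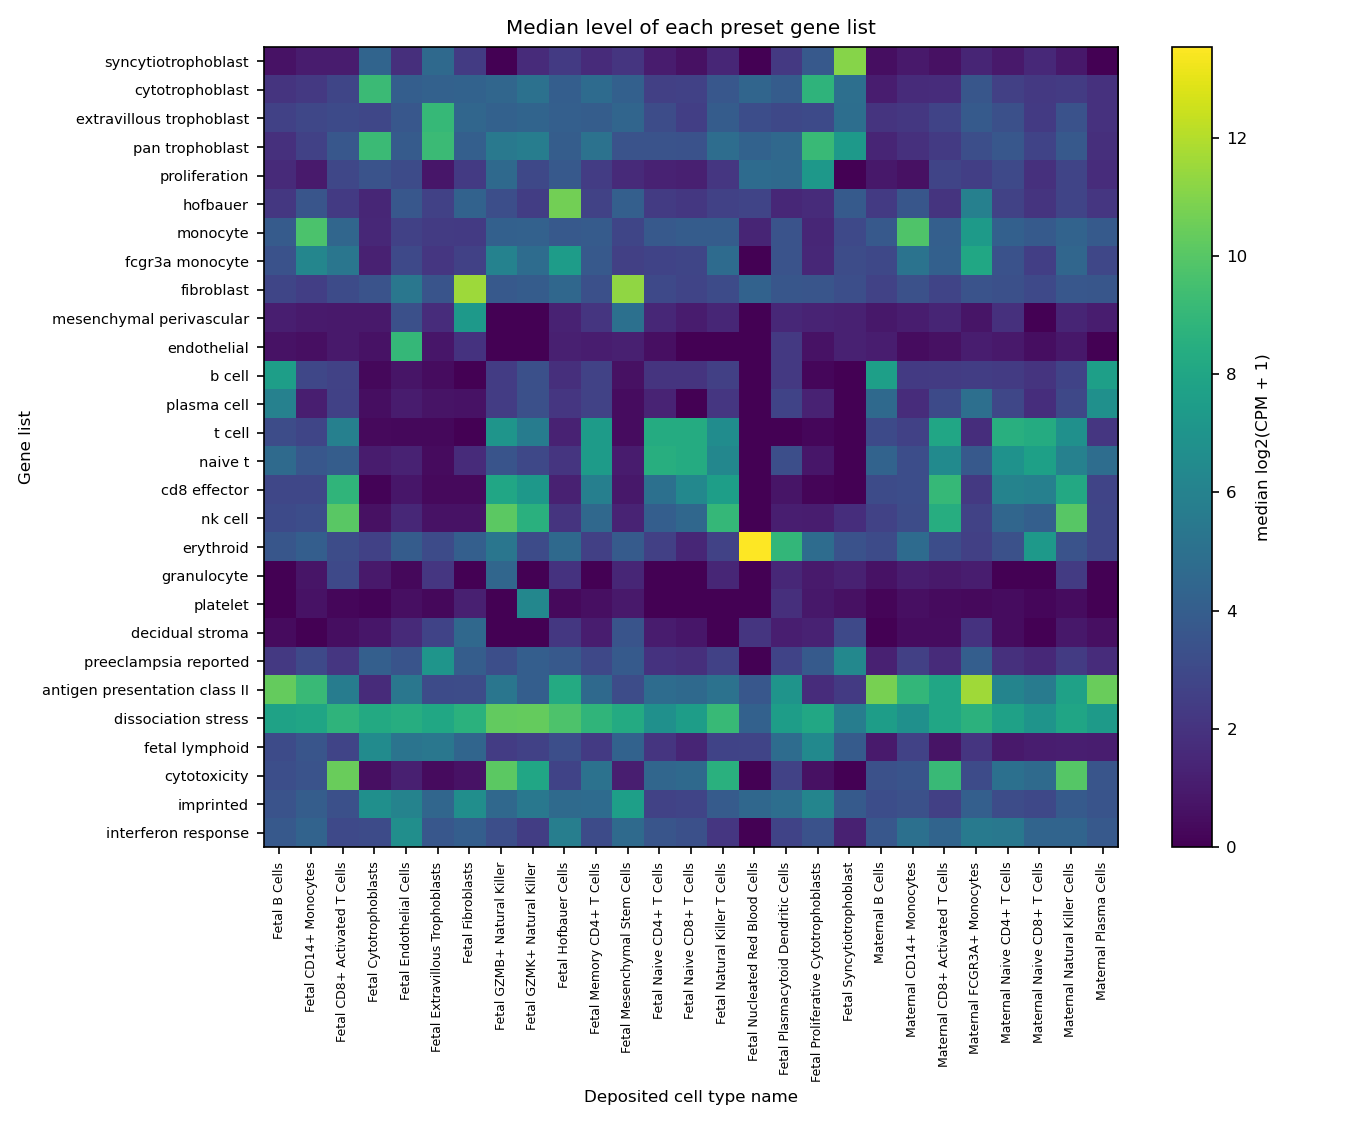
Colour gives the median log2(CPM + 1) of each of 28 gene lists (y axis) in each of the 27 cell types (x axis). The highest cell of the cytotrophoblast list is in cytotrophoblasts at 9.23, followed by proliferative cytotrophoblasts at 8.83, while the fibroblast list is near equal in fibroblasts at 11.53 and mesenchymal stem cells at 11.28.

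The first comparison asked what separates the 4 trophoblast types. Each of the other 3 types stood apart from cytotrophoblasts by a list fixed for it, which was the syncytiotrophoblast, the extravillous or the proliferation list. In syncytiotrophoblast against cytotrophoblasts, 24 of 28 measured genes of the syncytiotrophoblast list were at least 2-fold higher and 1 was lower, with a median log2 ratio of 8.002, above all 10000 random lists. In extravillous trophoblasts, all 15 eligible genes of the extravillous list were higher, with a median of 6.11. Of 15 eligible proliferation genes, 14 were higher in proliferative cytotrophoblasts, with a median of 4.21. The labels do not say whether types were named by markers like these. If they were, a list standing highest in its own type was fixed in advance, here and in the comparisons below. A place above the random lists would then give no separate support for the name.

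The syncytiotrophoblast genes were led by CSH2, a second placental lactogen gene on chromosome 17 (63872012 to 63873766, minus strand). It reached 28841 CPM (28458 to 29227) against 32.8 CPM (30.8 to 34.8) in extravillous trophoblasts, a log2 ratio of 9.74. CSHL1 and PSG1 followed with log2 ratios of 9.65 and 8.89 to the highest other type. KISS1, the precursor of kisspeptin, stood at 9291 CPM against 23.3 in cytotrophoblasts (8.58), and LINC00967, a long noncoding RNA, at 734 CPM against 1.09 in extravillous trophoblasts (8.46). GH2, the placental growth hormone gene, came next at 8.25, and CGB3, the gene for the chorionic gonadotropin beta chain, at 8.03. The chorionic gonadotropin alpha chain gene CGA was also abundant in cytotrophoblasts, at 4891 CPM against 55667 in syncytiotrophoblast. CYP19A1, the aromatase that makes estrogens, was higher in syncytiotrophoblast by a log2 ratio of 2.76, and TFPI2, a protease inhibitor, by 8.68. The 1 listed gene that was lower was ERVFRD-1, which encodes the fusogen syncytin-2, with a log2 ratio of -1.18, and ERVW-1, which encodes syncytin-1, was within 2-fold at -0.41. Both lie near the median of all eligible genes in this pair, -0.87, so these 2 calls depend on scaling. Genes of the CSH, GH2, CGB and PSG families are near copies of one another, so the split of counts within a family is uncertain.

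Cytotrophoblast genes were low in both differentiated types. Of 13 eligible genes of the cytotrophoblast list, 12 were at least 2-fold lower in syncytiotrophoblast (median -4.85) and 12 in extravillous trophoblasts (median -4.79), below all random lists in each case. PAGE4 was 12542 CPM in cytotrophoblasts, 435 in syncytiotrophoblast and 140 in extravillous trophoblasts, and PEG10, an imprinted gene of retroviral origin, was 3055, 46.5 and 18.9 CPM. All 5 eligible imprinted genes were lower in syncytiotrophoblast (median -4.95). In extravillous trophoblasts, 3 were lower and 1, the noncoding RNA H19, was higher at 7183 CPM against 1467. Genes of the stress response to dissociation were lower in syncytiotrophoblast, where 12 of 13 were at least 2-fold lower (median -2.08), among them JUN at -5.16 and HSPA1A at -2.17. Of 3 eligible monocyte genes, 2 were higher there (median 2.90), CD14 at 125 CPM against 4.82 and S100A9 at 1432 against 191 CPM, while CSF3R was within 2-fold at 259 against 444 CPM. The general trophoblast list, which holds keratins and GATA3, had a median of -0.98 in syncytiotrophoblast and -0.06 in extravillous trophoblasts.

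In extravillous trophoblasts, PRG2, which encodes the proform of eosinophil major basic protein, alone made up 231468 CPM, against 1395 in cytotrophoblasts. FN1, which encodes fibronectin, was 24696 CPM against 377, HLA-G 2423 against 20.2, and MMP2, a matrix metalloproteinase, 343 against 2.80. By the naming rule the leading genes were IL2RB, the interleukin 2 receptor beta chain (chromosome 22, 37118666 to 37175118, minus strand), at 276 CPM (270 to 282) against 1.96 (1.51 to 2.49) in cytotrophoblasts, and the decoy receptor IL1R2 at 202 against 1.46. TNFSF10, the death ligand TRAIL, stood at 1254 CPM against 16.0 in syncytiotrophoblast. TAC3, the precursor of neurokinin B, reached 9785 CPM against 137 there. IL18BP, which neutralises interleukin 18, had 1 count in syncytiotrophoblast, which leaves its fold of 128 between 23.0 and 5059. LHFPL6 and LINC02246 completed the set at 179 and 304 CPM. The extravillous cells also held 3 of 4 eligible red cell genes at a higher level than cytotrophoblasts (median 1.83), including HBG1 at 101 CPM against 25.9. Globin RNA was also found in cells that should lack it, such as maternal B cells, with HBB at 954 CPM. Expression by the trophoblasts themselves is therefore not shown, and the source of these counts was not tested.

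Proliferative cytotrophoblasts kept the cytotrophoblast list within 2-fold for all 13 eligible genes (median -0.20). They were marked by CDK1, the mitotic kinase (chromosome 10, 60778331 to 60794852, plus strand), at 261 CPM (254 to 268) against 6.92 (6.06 to 7.88) in cytotrophoblasts, and by PBK, NUSAP1, TOP2A, UBE2C and BIRC5. MKI67 was found in 17.6% of these cells and 1.94% of cytotrophoblasts, at median depths of 2605.5 and 7893. Of 8 eligible syncytiotrophoblast genes, 7 were lower (median -2.03), among them CGA at 281 CPM against 4891. Red cell genes were higher, with 4 of 5 eligible at least 2-fold up (median 2.11), including HBG1 at 200.5 against 25.9 CPM. As in the extravillous cells, the source of this globin RNA was not tested. Genes that led cytotrophoblasts stood out less. EPS8L1, at 136 CPM against 45.7 in proliferative cytotrophoblasts, had the largest log2 ratio at 1.55, followed by ERVFRD-1 at 1.18 against syncytiotrophoblast and the iron exporter SLC40A1 at 1.17. MTRNR2L1, MTRNR2L12, MTRNR2L8 and TACC2 lay between 1.09 and 1.16, and the MTRNR2L genes resemble mitochondrial ribosomal RNA, whose reads they may share.

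Scaling moved the trophoblast ratios. CSH1 in syncytiotrophoblast and PRG2 in extravillous trophoblasts each took up a large part of the total. The median of all eligible genes was -0.87 in syncytiotrophoblast and -0.96 in extravillous trophoblasts against cytotrophoblasts, so the list medians relative to all genes were 8.88 and 7.07, and the general trophoblast list in extravillous cells changed sign. With totals without the most abundant genes, the medians of all eligible genes were -0.32 and -0.43. Leaving those genes out thus removed part of the shift and not all of it. With median-of-ratios size factors, the share of genes higher than in cytotrophoblasts went from 24.9% to 48.6% in syncytiotrophoblast. In extravillous trophoblasts it went from 22.5% to 50.6%. Those factors centre the ratios of genes found in both types, so a near even split was largely built in.

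Stromal and endothelial types were compared next, to show which transcripts separate the cells of the villous core. The perivascular list was higher in the cells named fibroblasts than in those named mesenchymal stem cells, and the endothelial and interferon-response lists were higher in endothelial cells than in mesenchymal stem cells. Of 7 eligible genes of the perivascular list, 6 were at least 2-fold higher in fibroblasts than in mesenchymal stem cells, with a median log2 ratio of 4.34, above all random lists. The fibroblast list itself had a median of -0.23, with 2 of 10 genes higher and 2 lower. All 11 endothelial genes were higher in endothelial cells than in mesenchymal stem cells, with a median of 7.43, and all 10 fibroblast genes were lower, with a median of -5.13.

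ACTA2, the smooth muscle actin on chromosome 10 (88935074 to 88991339, minus strand), was 13633 CPM (13457 to 13810) in fibroblasts and 373 (366 to 381) in mesenchymal stem cells. It was found in 92.2% of fibroblasts and 23.9% of mesenchymal stem cells, at median depths of 1307.5 and 1682 counts. ACTG2, the enteric smooth muscle actin, was 2069 CPM against 9.23, CNN1, which encodes calponin, 321 against 0.766, and MYH11, the smooth muscle myosin heavy chain, 306 against 8.72 CPM in endothelial cells. These 3 genes were found in 44.8%, 22.3% and 21.3% of fibroblasts. MUSTN1, CYFIP2, RGN and AOC3 completed the set with log2 ratios from 4.83 to 6.80. Genes of the fibroblast list split. COL1A1 was higher in fibroblasts at 6973 CPM against 2408, while LUM, which encodes lumican, and PDGFRA were higher in mesenchymal stem cells, with log2 ratios of -1.32 and -1.06 for fibroblasts. Mesenchymal stem cells were led by NEBL at 92.7 CPM against 3.56 in fibroblasts, and by TNFSF13B, the B cell activating factor, at 115 against 4.75. The chemokine CXCL14 (1392 against 132 CPM), the lipid carrier APOE (881 against 78.9), the hyaluronan link protein HAPLN1 (773 against 70.6) and DPT, which encodes dermatopontin (313 against 34.4), were among the rest, with TSHZ2 and LINC01140. Genes of the stress response to dissociation were slightly higher in fibroblasts (median 0.42, percentile 99.7), with 1 of 12 beyond 2-fold.

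Endothelial cells were led by CDH5, which encodes VE-cadherin (chromosome 16, 66366690 to 66404784, plus strand), at 573 CPM (552 to 595). It had 2 counts in fibroblasts, the highest other type, which leaves its fold of 483 between 134 and 3991. PECAM1 stood at 2129 CPM against 13.6 in fibroblasts, CD34 at 828 against 3.56, and FCGR2B, an inhibitory receptor for IgG, at 2761 against 14.8. ECSCR, NRN1, PLVAP and ITM2A completed the set, with PLVAP and ITM2A at 2 counts and 1 count in fibroblasts. All 6 eligible interferon-response genes were higher than in mesenchymal stem cells (median 2.39), among them ISG15 at 596 against 92.9 CPM and IFI44L at 102 against 3.41. The median of all eligible genes was 0.24 in this pair, well below these values.

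Hofbauer cells were compared with maternal monocytes to separate the fetal macrophages of the villus from maternal myeloid cells. All 15 Hofbauer genes were at least 2-fold higher in Hofbauer cells (median 5.61), and 9 of 10 monocyte genes were lower (median -5.13), the 1 exception being higher. LYVE1, a hyaluronan receptor on chromosome 11 (10556966 to 10611689, minus strand), was 1260 CPM (1230 to 1290) against 2.54 (1.69 to 3.67). It was found in 71.3% of Hofbauer cells and 1.05% of maternal monocytes, although the median depth was 1283 counts in Hofbauer cells against 5246.5 and 3553 in the CD14+ and FCGR3A+ monocytes. S100A12, an inflammatory calcium-binding protein, led in the other direction at 719 CPM (703 to 735) against 1.85 (0.889 to 3.41).

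Among the other Hofbauer genes, RNASE1, a secreted ribonuclease, was 7943 CPM against 81.2, the selenium carrier SELENOP 6146 against 72.0, the phospholipid transfer protein PLTP 4500 against 67.0, and the folate receptor FOLR2 2615 against 36.6. F13A1, the coagulation factor XIII A chain, had a log2 ratio of 6.84, FCGBP 7.66, the chemokine CCL13 6.78 and C4BPB, a subunit of the complement regulator C4b-binding protein, 6.83. EGFL7, the prostaglandin D synthase HPGDS, and LARGE1 completed the 12 genes, the last with 2 counts in monocytes. Maternal monocytes carried G0S2 at 2502 CPM against 11.5, the chemokine CCL20 at 1371 against 6.49, S100A8 at 4684 against 47.5, and the lectin FCN1 at 1250 against 14.1. EREG, a growth factor of the EGF family, the cytidine deaminase APOBEC3A, LGALS2, AQP9, CFP, which encodes properdin, and CD300E had log2 ratios between 5.93 and 7.30, and TNFAIP6 had 3 counts in Hofbauer cells. Genes of class II antigen presentation were lower in Hofbauer cells for 5 of 6 (median -1.58), with HLA-DRA at 1304 against 5327 CPM. Genes of the stress response to dissociation were higher for 7 of 13 (median 1.41), such as HSPA1A at 3004 against 446 and JUN at 871 against 204.

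The Hofbauer ratios depended on scaling and on the reference cells. With median-of-ratios size factors, the median of all genes moved from -0.06 to -0.63 and the share of genes higher in Hofbauer cells from 47.6% to 29.1%. With totals without the most abundant genes, that median was -0.08. Against CD14+ monocytes alone, a choice made after the data were seen, the Hofbauer list had a median of 7.62, and FCGR3A+ maternal monocytes carried Hofbauer genes, such as C1QA at 1229 CPM against 28.5 in CD14+ cells.

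Lymphocytes named for both origins were compared to find transcripts that separate fetal from maternal cells of the same name. B cells, naive CD4+ T cells, naive CD8+ T cells and CD8+ activated T cells were available from both. The last pair differed in T cell transcripts, since at 1000 counts per cell a CD3D, CD3G or TRAC count was found in 21.3% of the fetal and 71.6% of the maternal cells, against 15.2% of maternal natural killer cells. A ranking over the 4 pairs therefore does not compare like cells throughout. The naive CD4+ T pair may be unlike as well. In whole profile, its maternal cells were closer to maternal CD8+ activated T cells (correlation 0.951) than to its fetal cells (0.936). SOX4, a transcription factor gene on chromosome 6 (21593751 to 21598619, plus strand), was higher in the fetal cells of all 4 types, with log2 ratios of 2.69, 5.10, 3.75 and 2.97 in that order. It was 346 CPM in fetal and 9.09 CPM in maternal naive CD4+ T cells, from 1526 and 10 counts, and 138 and 20.5 CPM in B cells. LSR, a lipoprotein receptor gene on chromosome 19 (35248330 to 35267964, plus strand), was higher in the maternal cells of all 4, with log2 ratios of -2.65, -2.37, -1.88 and -2.64. The rule required the same direction in all 4 types, so that agreement is not separate support. The 4 types may also share the same placentas, so a difference between people or libraries could appear in all of them.

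The other genes of fetal cells differed less. ARHGEF7, an exchange factor for Rho GTPases, had a smallest log2 ratio of 0.93 over the 4 types, the ganglioside synthase ST3GAL5 0.71 and the heat shock gene HSPB1 0.69. PRKACB, UBE2F, HES4, SRPK2, CTSL and BZW2 lay between 0.61 and 0.65. On the maternal side, the genes were YWHAH, the metallothionein MT1F, TSPO, DYNLT3, STAT1, ARID5B and FAM118A, with the value nearest 0 between -1.02 and -0.70. STAT1, which carries interferon signals, was 32.9 CPM in maternal and 19.7 CPM in fetal B cells and 137 against 70.3 CPM in naive CD4+ T cells. The rule also named HBA2 and HBB, red cell globin genes, whose log2 ratios were -6.70 and -6.87 in naive CD8+ T cells. There, 5 cells held 99.1% of the HBA2 counts and 99.3% of the HBB counts of the maternal type, and without the 5% deepest cells neither gene kept its direction in all 4 types.

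**Figure D3:**
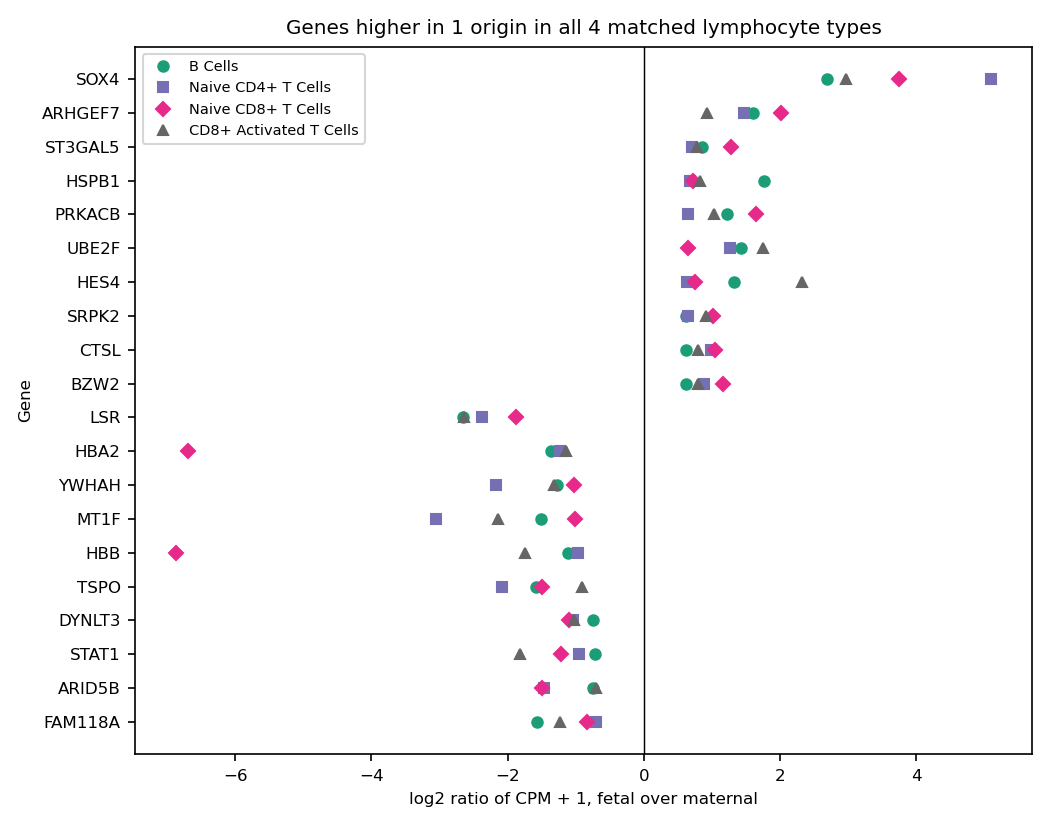
Points give the log2 ratio of CPM + 1, fetal over maternal (x axis), for the 20 named genes (y axis) in each of the 4 matched lymphocyte types. SOX4 lies farthest to the right, from 2.69 to 5.10, and HBA2 and HBB reach -6.70 and -6.87 in naive CD8+ T cells alone.

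List members moved by type. In B cells, all 3 eligible genes of the fetal lymphoid list were higher in fetal cells (median 2.69), including the RNA-binding protein gene IGF2BP3 at 56.8 against 0.844 CPM, and 2 of 3 plasma cell genes were higher (median 1.75). In naive CD4+ T cells, the naive T cell list was higher in fetal cells for 3 of 6 genes (median 0.80), with the homing receptor genes SELL at 561 against 142 CPM and CCR7 at 592 against 258, and LEF1 at 233 against 53.7. The CD8 effector list was lower there for 2 of 3 genes (median -3.08), with GZMK at 8.16 against 76.4 CPM, as were the cytotoxicity list for 2 of 3 (median -1.54) and the class II list for 2 of 4 (median -1.04). Genes of the stress response to dissociation were also lower in these fetal cells, for 4 of 9 (median -0.89, percentile 0.13), with FOS at 182 against 468 CPM. Since the maternal naive CD4+ T cells were closest in profile to maternal CD8+ activated T cells, these may not be differences within 1 kind of cell. In naive CD8+ T cells, 5 of 6 naive genes were within 2-fold (median 0.47), as were all 9 stress genes (median 0.61). The stress list had a median of 0.28 in B cells and 0.27 in CD8+ activated T cells.

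The cells named fetal CD8+ activated T cells carried natural killer genes, with NKG7 in 98.9% at 1000 counts per cell, and few T cell transcripts, so their differences from the maternal cells are not differences within 1 kind of cell. All 7 eligible natural killer genes were higher in the fetal cells (median 1.73), such as KLRF1 at 613 against 32.9 CPM and GNLY, which encodes granulysin, at 4134 against 840. Of 7 T cell genes, 6 were lower (median -2.15), with the T cell receptor constant gene TRAC at 23.4 against 492 CPM and the CD8 beta chain gene CD8B at 11.3 against 193. The cytotoxicity list was higher for 5 of 7 genes and lower for 1 (median 1.30). In this pair the median of all eligible genes was 0.35, and 0.24 with totals without the most abundant genes. The share of genes higher in fetal cells went from 76.97% to 47.3% with median-of-ratios size factors, which largely build in a near even split. Only 2 of the 20 named lymphocyte genes were still named with no filter on low values, 10 with each cell thinned to 1000 counts, and 11 without the CD8+ activated T pair, the last a choice made after the data were seen.

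Genes reported as changed in preeclampsia placentas, the disorder in the study's title, were located by cell type, although no labels describe a preeclampsia sample. Of 19 such genes, 16 had their highest level in a trophoblast type, with 11 in extravillous trophoblasts, 4 in syncytiotrophoblast and 1 in cytotrophoblasts. PAPPA2 and HTRA4 are also on the extravillous list and CRH on the syncytiotrophoblast list, so part of this count follows from the choice of genes. The share of all genes that were highest in a trophoblast type was not computed, so the count does not set these genes apart. Syncytiotrophoblast was represented by only 384 cells, at a median of 1236.5 counts. FLT1, the vascular endothelial growth factor receptor gene whose soluble product is measured in preeclampsia (chromosome 13, 28300346 to 28495145, minus strand), was 2656 CPM (2638 to 2673) in extravillous trophoblasts and 322 CPM in cytotrophoblasts, the next type, a log2 ratio of 3.04. Counts were per gene and do not separate the soluble form. PAPPA2, a protease of insulin-like growth factor binding proteins (chromosome 1, 176463171 to 176845601, plus strand), was 2009 CPM (1993 to 2024) in extravillous trophoblasts and 664 CPM in syncytiotrophoblast.

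The serine protease genes HTRA1 and HTRA4, the follistatin-like gene FSTL3, the inhibin gene INHA and QSOX1 were also highest in extravillous trophoblasts, at 1296, 128, 1216, 337 and 1533 CPM. EBI3, a cytokine subunit, was 2002 CPM there and 1408 CPM in syncytiotrophoblast. Another 2 of the 11 were nearly as high in leukocytes, NDRG1 at 131 CPM against 98.8 in fetal CD14+ monocytes and SH3BP5 at 116 CPM against 97.4 in maternal CD14+ monocytes. Syncytiotrophoblast was highest for PGF, the placental growth factor gene (859 CPM, 794 to 928), INHBA (412 CPM), the corticotropin-releasing hormone gene CRH (344 CPM) and LEP, the leptin gene. LEP rested on 52 counts found in 2.34% of syncytiotrophoblast cells. ENG, the endoglin gene, was shared, at 314 CPM in extravillous trophoblasts and 250.03 CPM in endothelial cells, and SIGLEC6 was highest in cytotrophoblasts at 221 CPM against 168 in proliferative cytotrophoblasts. Outside the trophoblasts, HK2 was highest in maternal CD14+ monocytes (49.7 CPM), BHLHE40 in maternal natural killer cells (229 CPM) and SASH1 in endothelial cells (48.8 CPM), each less than 2-fold above the next type. Against cytotrophoblasts, 8 of 11 eligible genes of the list were higher in syncytiotrophoblast and 2 lower (median 2.40), and 12 of 15 were higher in extravillous trophoblasts and 2 lower (median 4.31).

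**Figure D4:**
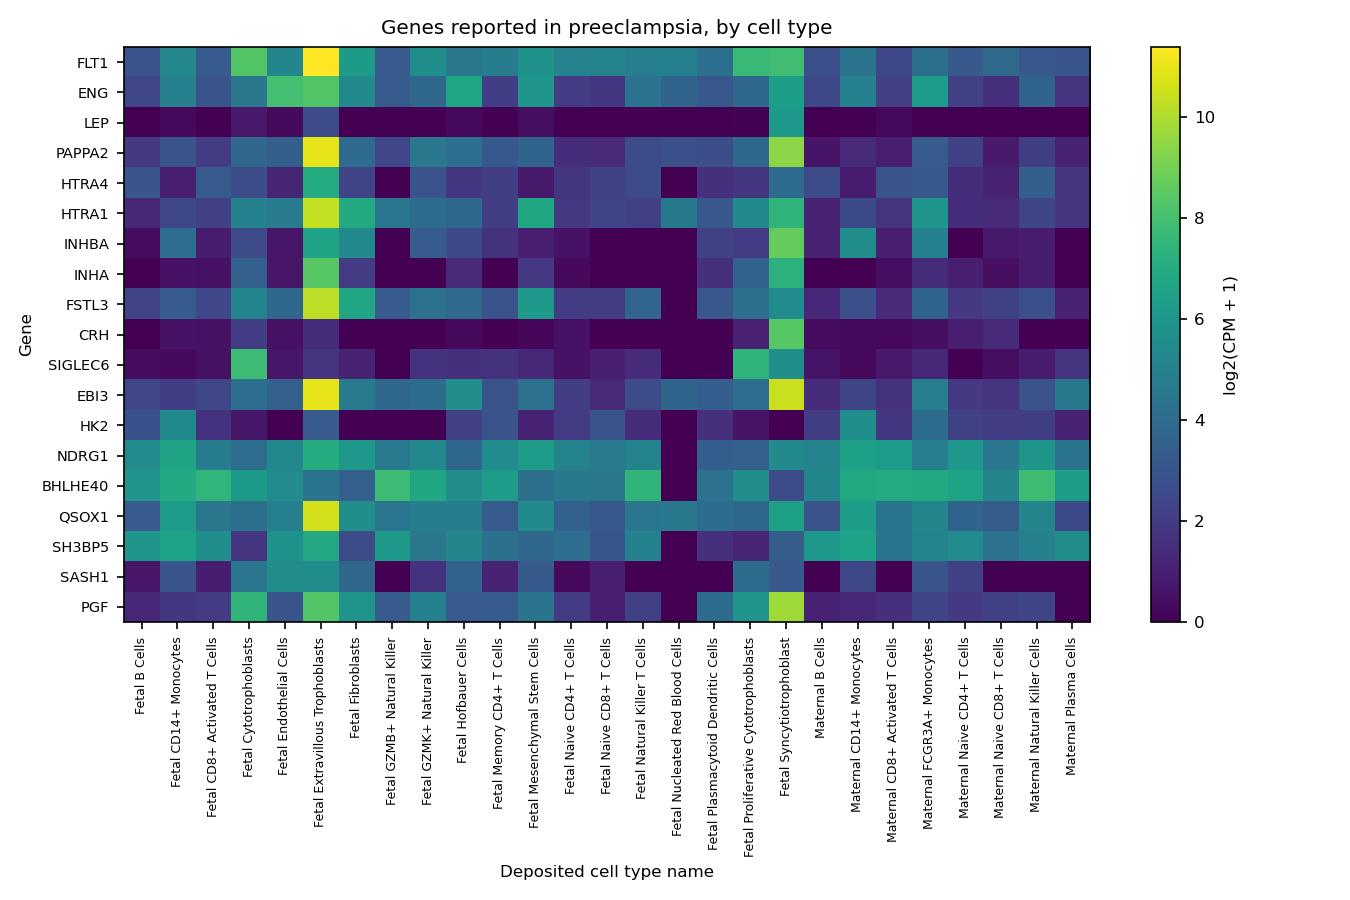
Colour gives log2(CPM + 1) of the 19 genes reported in preeclampsia (y axis) in each of the 27 cell types (x axis). The extravillous trophoblast column holds the highest value for 11 genes, with FLT1 at 2656 CPM, and syncytiotrophoblast for 4.

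Whole profiles were compared last, to show which types a reference of this kind would find hardest to tell apart. Over 12974 genes, 13 of the 27 types had a closest type with a correlation of at least 0.95, but none did with each type thinned to the total of the smallest. Fetal and maternal CD14+ monocytes were the closest pair at 0.982 (0.822 thinned), followed by cytotrophoblasts with proliferative cytotrophoblasts at 0.976 and fetal naive CD4+ with fetal naive CD8+ T cells at 0.974. For 8 types, the closest type had the other origin, and fetal and maternal B cells correlated at 0.968. Fetal CD8+ activated T cells were closest to maternal natural killer cells at 0.960 and slightly less close to maternal CD8+ activated T cells at 0.951. Hofbauer cells were closest to maternal FCGR3A+ monocytes at 0.890 and stood at 0.798 with maternal CD14+ monocytes. Mesenchymal stem cells and fibroblasts correlated at 0.941. Syncytiotrophoblast and extravillous trophoblasts were each other's closest type at 0.789, although syncytiotrophoblast stood at 0.788 with cytotrophoblasts. Under all 4 alternatives cytotrophoblasts were its closest type, at 0.808 and 0.790 over genes of at least 1 and 100 CPM, 0.777 by Spearman's coefficient and 0.686 thinned. By Spearman's coefficient extravillous trophoblasts were closest to cytotrophoblasts as well, at 0.768. Nucleated red blood cells were the most distinct, with a highest correlation of 0.641. These correlations are across genes, and in the thinned types the cytotrophoblast pair was the closest of all at 0.824.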

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

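Of the tests below, the one on free globin RNA was chosen only after its result was seen. Each result here is a signal in a cell type left out of the list comparisons of trophoblast, stromal, Hofbauer and matched lymphocyte types, at a level above what a count of 0 allows for that type. Which lists and types were looked at in this way was decided after the values were seen.

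Red cell transcripts were found in the cells named fetal plasmacytoid dendritic cells, where the erythroid list had a median of 8.97 on the log2(CPM + 1) scale and HBG2, a fetal globin gene, stood at 7801 CPM, against 61.2 CPM in fetal naive CD4+ T cells. Globin RNA spread evenly over the cells is argued against, since the 5 cells with the most HBG2 held 99.7% of its 4150 counts. Doublets among the deepest cells remain open, since without the 5% deepest cells of the type 26.4% of the HBG2 level was kept, between the bounds set beforehand for either answer, and a few red cells captured together with other cells may be a source. No biological explanation was tested.

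The platelet list had a median of 6.26 in fetal GZMK+ natural killer cells, where all 73 counts of PPBP came from 1 of 250 cells. The granulocyte list had a median of 4.49 in fetal GZMB+ natural killer cells, from 12 counts in 119 cells.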

How the results depend on the processing

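Each comparison was followed through the alternatives by 1 or more values, which were chosen after the data were seen, as were the 4 added choices. Of 88 alternatives to these values, 49 left the value within its counting interval (a count of genes or lists, within 1.5 times), 39 moved it and none changed its direction. A count of genes or lists, or a share of cells, could not have changed direction. A further 994 alternatives were for single named genes and for the number of types that kept their closest type. Of these, 738 stayed within the interval (for that number of types, within 1.5 times), 251 moved and 5 reversed. The intervals are narrow because they cover counting error only. The cause of the moves was not tested.

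Among the trophoblast types, the syncytiotrophoblast list in syncytiotrophoblast (median 8.002) was 6.38 by the mean of per-cell CPM, 6.27 and 8.11 with pseudocounts of 10 and 0.1 CPM, 8.59 without the most abundant genes, 8.72 with median-of-ratios size factors, 7.30 without the deepest cells, 8.13 in cells of at least 1000 counts and 6.83 with thinned cells. In extravillous trophoblasts, the extravillous list (6.11) was 5.75 by per-cell CPM, 4.79 with 10 CPM, 6.75 without abundant genes, 7.03 with size factors, 5.95 without the deepest cells and 5.83 thinned. Proliferation genes (4.21) were at 3.62, 2.84 and 4.40 by per-cell CPM and with 10 and 0.1 CPM, at 3.30 thinned and at 4.03 with no filter.

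The Hofbauer list (5.61) was 4.38 with 10 CPM, 5.03 with size factors and 7.62 against CD14+ monocytes alone. The perivascular list (4.34) was 3.18 with 10 CPM, and the endothelial list (7.43) was 5.25 and 8.38 with 10 and 0.1 CPM. SOX4, by its smallest ratio over the lymphocyte types (2.69), was 3.12 by per-cell CPM, 2.07 with 10 CPM and 3.14 without the deepest cells. FLT1 (3.04) was 3.25 by per-cell CPM, 3.00 with 10 CPM, 3.58 without abundant genes, 4.04 with size factors, 2.95 without the deepest cells and 3.14 thinned. Fetal cells (84.4%) made up 82.4% of those with at least 1000 counts. The correlation of the cytotrophoblast pair (0.976) was 0.978 and 0.983 over genes of at least 1 and 100 CPM, 0.970 by Spearman's coefficient and 0.824 with types thinned.

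Globin genes were the ones that reversed, with values below 0 for a gene named as higher in maternal cells. HBA2 fell to -0.18 in CD14+ monocytes and -1.19 in lymphocytes without the deepest cells, and HBB in lymphocytes to -0.043 by per-cell CPM, -1.52 without the deepest cells and -0.090 thinned. Which genes were named also depended on the setting. Of 28 trophoblast genes 16 were still named with thinned cells, but only 1 of 7 for cytotrophoblasts with no filter, 2 of 7 for them without the deepest cells and 2 of 7 for extravillous trophoblasts with 10 CPM. Of 24 stromal and endothelial genes 16 were with 10 CPM or with no filter, and 3 of 8 for mesenchymal stem cells with no filter and for endothelial cells with 0.1 CPM. Of 24 Hofbauer and monocyte genes 17 were with 10 CPM, thinned, or against CD14+ monocytes alone. In the last of these settings, 6 of 12 Hofbauer genes and 11 of 12 monocyte genes were still named. Without the naive CD8+ T pair, 12 of the 20 lymphocyte genes were still named. No paired analysis was possible because no column ties a cell to a library or placenta, and for the same reason leave-one-out and the replicate block were not run. Depth limits the smallest types most, since 3 counts amount to 17.3 CPM in nucleated red blood cells and 0.0903 CPM in cytotrophoblasts.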

Other observations

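The comparison of CD14+ monocytes, and the genes named below in other cell types, were chosen after their values were seen. So were the 4 tests on contractile genes in the fibroblasts and all 3 tests on the CD8+ activated T cells.

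Fetal and maternal CD14+ monocytes shared their monocyte genes, with all 10 listed genes within 2-fold (median -0.11). All 3 eligible interferon-response genes were lower in the fetal cells (median -1.48, percentile 0.04), among them ISG15 at 169 against 472 CPM and IFI44L at 8.41 against 53.8. GBP1, an interferon-induced GTPase, was 105 CPM in maternal and 8.89 CPM in fetal cells, STAT1 111 against 30.8, and TNF 187 against 64.4. Fetal cells were higher in CRIP1 (3067 against 1329 CPM), in CFD, the gene of complement factor D (655 against 257), and in S100P (89.9 against 29.3). The median of all genes moved from 0.00 to -0.13 with median-of-ratios size factors, less than these differences. Red cell genes moved with the pair, with HBB at 954 CPM in maternal and 37.5 in fetal cells and HBA2 at 624 against 89.9. Without the deepest cells the HBB log2 ratio went from 4.63 to 1.80 and HBA2 changed direction. The stress list had a median of 0.21 for fetal cells (percentile 99.4) with 1 of 10 genes beyond 2-fold, HSPA1A at 248 against 89.8 CPM, and the heat shock gene HSPB1 stood at 95.9 against 33.6. The gene with the largest ratio of all is not named, because its level can differ between people by genotype.

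Several types carried transcripts that their names do not bring to mind. Cells named fetal plasmacytoid dendritic cells had SPINK2 at 229 CPM (190 to 274), PRSS57 at 218 (180 to 262) and GATA2 at 111 (84.4 to 143), genes of blood progenitors, and no count of LILRA4, a plasmacytoid dendritic cell gene, which allows up to 5.64 CPM. SPINK2 was found in 33 and PRSS57 in 36 of the 104 cells. Other plasmacytoid dendritic cell genes are not given here, so the name of the group as a whole was not checked. Maternal FCGR3A+ monocytes held macrophage genes, with SPP1 at 11969 CPM, APOC1 at 5937 and TREM2 at 464, against 84.3, 29.3 and 1.44 CPM in maternal CD14+ monocytes. SPP1 was found in 52.2% of them and 16.2% of CD14+ cells, at median depths of 3553 and 5246.5. Maternal plasma cells had MS4A1, a B cell gene, at 374 CPM, much as in maternal B cells at 368, beside JCHAIN at 1586 against 72.6. Genes of the stress response to dissociation were highest in fetal GZMK+ and GZMB+ natural killer cells, with list medians of 10.33 and 10.29, and the heat shock gene HSPA6 stood at 2715 and 6490 CPM there against 396 in fetal CD8+ activated T cells.

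Contractile genes in the cells named fetal fibroblasts (ACTA2, TAGLN, ACTG2, CNN1 and MYH11) were weighed against 3 technical explanations. Free RNA is argued against because, at 1000 counts per cell, each gene was found in a share of these cells at least 4.73 times the higher of the shares in endothelial and mesenchymal stem cells, and doublets among the deepest cells because each log2 ratio to mesenchymal stem cells was still at least 4.48 without those cells. A minority of smooth muscle cells as the only cells with ACTA2 and TAGLN is argued against, since these were found in 90.9% and 93.9% of the group. Such shares do not show how evenly the level was spread. ACTA2 was in fewer cells than any of 3 genes of like level (CPM within 1.5 times), while 33.3% of 6 such genes were in fewer cells than TAGLN. A minority as the source of much of their level stays open. It also stays open for ACTG2, CNN1 and MYH11, found in 45.4%, 19.6% and 18.2%. ACTG2 was in fewer cells than any of 68 genes of like level, but 26.6% and 18.4% of the genes of like level were in fewer cells than CNN1 and MYH11. Doublets of ordinary depth were not tested, nor was any biological explanation.

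Natural killer genes in the cells named fetal CD8+ activated T cells were weighed in the same way. Free RNA is argued against, since NKG7 in fetal B cells was 0.646% of its level in these cells. Of the cells with NKG7, 21.5% also held a CD3D, CD3G or TRAC count at 1000 counts per cell, below the share set for doublets with T cells. That share was above the 72.8% reached by maternal CD8+ activated T cells with NKG7, so it could hardly be met. Doublets are therefore not excluded. A candidate explanation is that natural killer cells make up most of the group. In all, 21.3% of its cells held a count of any of the 3 T cell genes (18.7 to 24.2), near the 15.2% of maternal natural killer cells (11.9 to 19.04) and far from the 71.6% of maternal CD8+ activated T cells (69.3 to 73.8), with 1.92% in fetal B cells as background. Because 98.9% of the cells held NKG7, this share is nearly the same measure as the one used on doublets, and is not separate support. The design gives no group that bears on a biological explanation, so none was tested beyond this makeup of the group.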
